A study of Rattus norvegicus with 6 samples.

How the data were processed

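The deposited data were a single table of transcripts from 6 RNA-seq libraries of rat placental junctional zone, 3 from dams given vehicle (control) and 3 from dams given STZ. Per the labels' protocols, total RNA was isolated with TRIzol, libraries were made with Illumina TruSeq RNA kits and sequenced on a HiSeq2000 as 100-bp paired-end reads. Whether libraries came from separate dams, and whether conceptuses were pooled, was not stated.

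Per the file headers, the authors gave for each transcript and library a count of total transcript reads, a count of unique transcript reads (reads matching only that transcript) and an RPKM value, in the layout of the CLC Genomics Workbench. The aligner settings, its version and the use of strand were not stated, so reads of overlapping or antisense genes could not be told apart. The deposited RPKM values divide by a read number larger than the reads listed: the listed reads made up 59.5% of it in control replicate 1 and 42.1% to 49.3% in the other libraries. The table also holds the authors' signed fold change of mean RPKM, treated here as a deposited score and not used, and transcript lengths, another deposited column that is not a measurement. The submitters' processing notes name the genome build Rnor 5.0, but the table lists 24 transcripts on a Y chromosome, which that assembly lacks, so the build is uncertain and positions are given as in the deposited table, counted from 1.

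Counts were summed from 33349 transcripts to 26088 genes with Python 3.11.15 and pandas 2.3.3, because the table holds transcript reads and the analysis had been planned for gene reads. A total of 20037 genes had at least 1 read, 0 rows named no gene and 0 sample columns belonged to no sample. Where a symbol served more than 1 gene identifier (9 cases), the plain symbol was kept for the gene with the most reads. Of 560 genes in the fixed lists, 530 matched by symbol, 7 by a synonym in a RefSeq table of assembly GRCr8 (used for names only) and 23 had no match.

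The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, the quasi-likelihood F test of STZ against control (two-sided, no covariate), and Benjamini-Hochberg adjustment over all genes tested at 0.05. TMM factors were 1.03 for each control and 0.808, 1.09 and 1.04 for STZ replicates 1 to 3. CPM values are TMM-normalised, and a standard error is the log2 fold change divided by the square root of its F statistic. Gene lists of at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 33 lists, and again with an estimated correlation and with fry, which tests whether the members of a list move on balance in one direction. Principal components used the 500 most variable genes. With 3 libraries against 3, values without error bars are given per library.

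The gene lists, tests and alternatives were chosen before the data were examined. Named genes followed a fixed rule. If none passed the threshold, it took the 10 smallest p-values, applied here in each direction, among genes of at least 1 CPM in the higher group, with no overlap between groups and a symbol that is not a placeholder. It also took up to 4 members of the smallest p per list and a set of 19 junctional zone, metabolic and vascular genes. Genes picked after their values were seen are said to be so.

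Alternatives were DESeq2 1.42.0, limma-voom, glmTreat against a fold change of 1.5, other normalisations (DESeq2 size factors, library totals alone, the 20 most abundant genes left out of library sizes), other filters (none, or 1 CPM in 3 libraries), unique reads, limma on log2(RPKM + 1) and log2(RPKM + 0.1) for genes of a mean RPKM of at least 1, a replicate block, each library left out in turn, and other thresholds. Added after seeing the data were DESeq2 without STZ replicate 1, limma-voom with sample quality weights, camera with an estimated correlation without STZ replicate 1, and principal components with each library left out. The fits were tested on simulated counts for the comparison of STZ with control, drawn from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. Each gene had the same dispersion in all libraries, so no simulated library stood apart. At 4-fold, edgeR recovered 54%, DESeq2 92% and limma-voom 55%, with 5, 43 and 5 false calls. With STZ replicate 1 left out, edgeR recovered 98% at 4-fold and 67% at 2-fold. Counting intervals are exact binomial intervals at 95%, and a group at 0 reads was given a floor of 3 reads. PCR duplicates are not marked, so intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9.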

Results

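RNA was sequenced from the junctional zone of the rat placenta, the layer of trophoblast cells between the maternal decidua and the labyrinth, which holds spongiotrophoblast cells, glycogen trophoblast cells and trophoblast giant cells. Holtzman Sprague-Dawley females had received 45 mg/kg streptozotocin (STZ), a toxin of the insulin-producing beta cells used to make rats diabetic, or citrate vehicle on gestation day 6.5. There were 3 control and 3 STZ libraries. The day of dissection was given as gestation day 13.5 in the sample characteristics and the series description but as 18.5 in the extraction protocol, so the stage of the tissue was not settled by the labels. Reads listed per library were 13185888, 10612504 and 8466182 for control replicates 1 to 3 and 10744260, 10627311 and 8108505 for STZ replicates 1 to 3. At these depths, 3 reads corresponded to between 0.228 and 0.370 CPM, a read count scaled to the total of its library.

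The libraries did not separate by group alone. STZ replicate 1 stood apart from the other 5 libraries, with a Spearman correlation across genes of 0.866 to 0.903 with them, against at least 0.978 between any other pair. Control replicates 2 and 3 were the closest pair (0.994), while control replicate 1 correlated at 0.9795 and 0.979 with them. The controls were thus not equally distant from each other, and whether replicates 2 and 3 shared a source was not stated. Genes are not independent replicates, so these values describe the libraries. The first principal component of the 500 most variable genes carried 71.9% of their variance and placed STZ replicate 1 at 65.2, STZ replicate 2 at 4.93 and the other libraries between -18.3 and -15.8. Leaving out that library, the first component carried 38.2% and placed the 3 controls between -18.3 and -9.55 and the remaining STZ libraries at 21.5 and 18.3. Markers of the maternal decidua averaged 2.58 log2 units above the control mean in STZ replicate 1, 0.74 in STZ replicate 2 and 0.29 in STZ replicate 3. Desmin (Des), an intermediate filament protein of decidual and muscle cells, was at 7288 CPM in STZ replicate 1 against 532 ± 64.4 CPM in control (mean ± SD, n = 3), and the serine protease Htra3 at 592 against 1.57 ± 0.527 CPM. The trophoblast keratins Krt8 and Krt18 took 0.107% and 0.0989% of the reads of that library, against at least 0.344% and 0.327% in each of the others.

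The comparison of STZ with control asked how exposure to maternal diabetes altered gene expression in the junctional zone. Several prolactin family hormones and spongiotrophoblast markers were lower in STZ: every STZ library lay below every control for 10 of 19 and 7 of 14 members of these lists, and above every control for 0 and 2, where chance puts 10% of genes without overlap in either direction. Markers of leukocytes and uterine natural killer cells were higher as lists. These 4 lists passed with a preset correlation between genes and none did with an estimated one (adjusted p = 0.530 for each). Prl8a5, a placental hormone of the prolactin family, measured 588 ± 227 CPM in control and 35.0 ± 7.72 CPM in STZ (mean ± SD, n = 3 each), a log2 fold change of -4.07 ± 0.39 (SE). Prl8a7, of the same family, measured 377 ± 78.2 and 22.6 ± 10.0 CPM (-4.06 ± 0.41). Tpbpa, the standard marker of spongiotrophoblast, measured 802 ± 316 CPM in control and 32.6, 109 and 108 CPM in STZ replicates 1 to 3 (-3.27 ± 0.57). On the higher side, Alox15, a lipoxygenase that oxidises polyunsaturated fatty acids, measured 7.84 ± 1.21 and 35.9 ± 8.38 CPM (2.19 ± 0.25).

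No single gene passed the threshold over all genes in the main test. Of 13060 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, the smallest adjusted p being 0.0984. At an unadjusted p under 0.05 there were 1007 genes, 649 higher and 358 lower in STZ, where 653 would be reached with no effect. DESeq2 called 100 genes, 55 higher and 45 lower. In 1030 genes every STZ library was above every control and in 1263 every STZ library was below, together 17.6% of genes against 10% by chance. When STZ replicate 1 was left out, edgeR called 1 gene, Prl8a7 (log2 fold change -3.76, adjusted p = 0.0219, against 1.65e-54 to 0.538 over all its alternatives), and DESeq2 called 210, of which 60 were among its 100 calls from the 6 libraries, all 60 in the same direction. The common biological coefficient of variation was 0.355 with the 6 libraries and 0.177 without STZ replicate 1. In the self-test on simulated counts with the spread of the 6 libraries, 12795 genes were tested and edgeR recovered 54% of genes changed 4-fold and 1% of those changed 2-fold. No simulated library stood apart as STZ replicate 1 did, so these shares may not hold for the real libraries.

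The genes with the smallest p in each direction are given as not passing. On the lower side they were, besides Prl8a5 and Prl8a7, Pappa2, a protease that cleaves insulin-like growth factor binding proteins, at 486 ± 147 CPM in control and 95.5 ± 13.9 in STZ (-2.35 ± 0.28), Creg1 (-2.21 ± 0.33), Rcsd1 (-2.40 ± 0.33), Chsy3, a chondroitin synthase (-2.63 ± 0.41), Prl3d4 (-3.31 ± 0.48) and the deubiquitinase Uchl1 (-1.48 ± 0.20). DESeq2 gave each of these genes an adjusted p of at most 6.88e-06. On the higher side, besides Alox15, they were Bmp2 (2.26 ± 0.47), the neutrophil collagenase Mmp8 (3.67 ± 0.65), the leukocyte integrin Itgal (2.06 ± 0.39), perforin (Prf1, 2.57 ± 0.56), the granzyme Gzmbl2 (2.16 ± 0.46), Ralgps2 (0.92 ± 0.16), Ash1l (0.67 ± 0.14) and Kank1 (0.79 ± 0.17). Mmp8 had 6 reads over the control group and 70 over STZ, so its fold change rested on control counts near the floor. It lay at 3.80, 2.42 and 1.06 CPM in STZ replicates 1 to 3. Prf1 went to 1.67 and Gzmbl2 to 1.53 without STZ replicate 1. Gzmbl2 was at 88.4 CPM in that library and at 30.7 and 35.4 CPM in the other STZ libraries. Under 1% of the reads of Gzmbl2 were unique to a transcript (0.773% in control), so its value rested on reads shared with other transcripts. For Ash1l the share was 13.1%, and with unique reads alone its log2 fold change was 0.73.

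The remaining genes of this ranking, Echs1, Fam50a and Actg1, switched between high and near-zero read counts. Echs1, a mitochondrial enzyme of fatty acid oxidation, had 0 reads in control and 356 in STZ, which is at least 137-fold higher when the control group is set to a floor of 3 reads over the group. Fam50a had 422 reads in control and 1 in STZ (ratio 365, 95% counting interval 65.1 to 14430), and gamma actin (Actg1) had 3241 and 12 (ratio 233, interval 133 to 452). The STZ reads of both were in STZ replicate 1. These limits and intervals cover counting error only. Unique reads made up 0.843% of the STZ reads of Echs1, 1.19% of the control reads of Fam50a and 0.0926% of those of Actg1, so the levels of these 3 genes depended on how shared reads had been assigned.

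Positions were as in the deposited table, whose genome build is uncertain. Prl8a5 (ENSRNOG00000016871) lay on chromosome 17 from 39188311 to 39463715, Prl8a7 on the same chromosome from 39509516 to 39515412, Prl3d4 from 42920890 to 42927704 and Tpbpa from 4165041 to 4167411, near the cathepsin genes Cts7 (3280311 to 3285451) and Ctsm (3820606 to 3826015). Pappa2 lay on chromosome 13 from 76389150 to 76660245, Alox15 on chromosome 10 from 56953691 to 56962161 and Prf1 on chromosome 20 from 30915213 to 30921382.

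**Figure D1:**
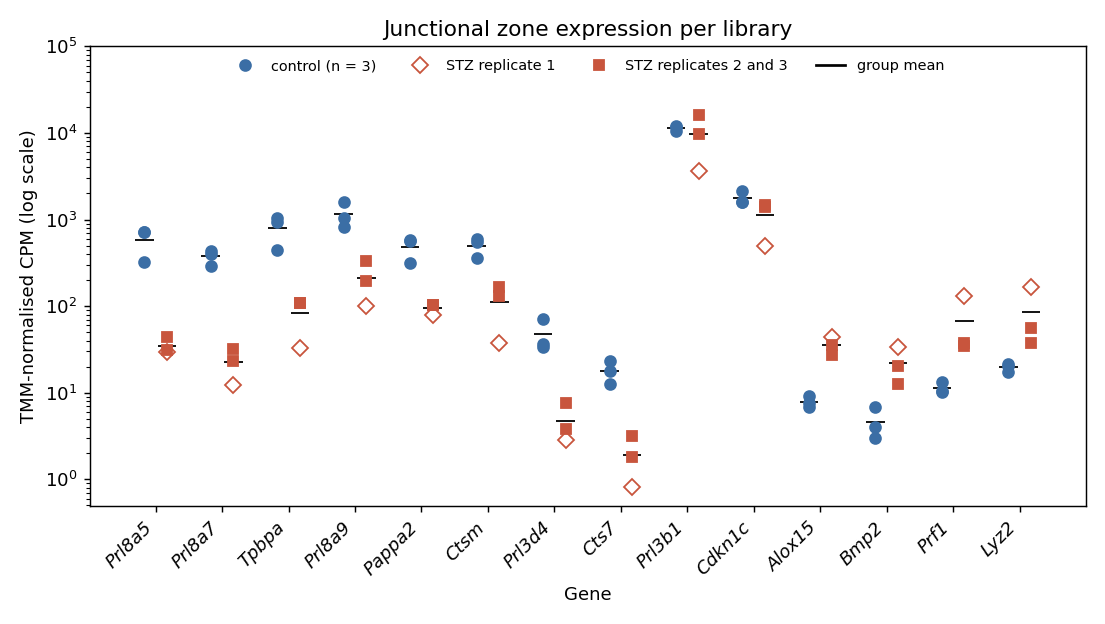
Expression of 14 genes per library, as TMM-normalised CPM on a log axis, with controls as filled circles, STZ replicate 1 as open diamonds, STZ replicates 2 and 3 as filled squares and group means as black lines. Prl8a5 lay at 29.6 to 43.9 CPM in the STZ libraries against at least 326 in the controls, while Prl3b1 ranged from 3603 to 16040 in STZ, on both sides of the control mean of 11420.

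Of the 33 gene lists fixed before the data were examined, 17 passed an adjusted p of 0.05 in camera with the preset correlation, 11 higher and 6 lower in STZ. None of the 33 passed with a correlation estimated from the data, where the smallest adjusted p was 0.530 and 1 list had an unadjusted p under 0.05, and none passed in fry, where 5 did. With the estimated correlation that 1 list was the prolactin family (unadjusted p = 0.0336). Lists of unlike unadjusted p share the adjusted p of 0.530, among them endothelial markers (unadjusted p = 0.285). Without STZ replicate 1, 10 lists passed, and 6 of the 17 were among them with the same direction. Over all genes 0 members of any list passed in edgeR, so the counts below are those adjusted over the list alone.

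The prolactin family list fell (adjusted p = 1.15e-08; adjusted p = 0.530 with an estimated correlation; 1.48e-08 without STZ replicate 1). Of its 19 measured members, 16 were lower and 3 higher, with a median log2 fold change of -0.84. Adjusted over the list alone, 6 members fell and 0 rose: Prl8a5, Prl8a7, Prl3d4, Prl7a4 (-2.66 ± 0.50), Prl8a9 (-2.45 ± 0.49) and Prl2b1. Without STZ replicate 1, 12 members fell and 1 rose in this way, the latter Prl3d2 (0.51). The family did not move as a block. Prl3b1, placental lactogen II and the most abundant of the fixed hormone genes, measured 11420 ± 691 CPM in control and 9804 ± 6218 in STZ (-0.22 ± 0.51, adjusted p = 0.865), Prl7b1 -0.46 ± 0.29 and Prl5a1 -0.46 ± 0.30 on the log2 scale. Prl3b1 took 0.291%, 1.06% and 1.67% of the reads of STZ replicates 1 to 3, against 1.10% to 1.24% in the controls. Prl8a2, which decidual cells also make, was at 2088 ± 317 CPM in control and at 7918, 1493 and 1415 CPM in STZ replicates 1 to 3, so that its log2 fold change went from 0.79 to -0.51 without STZ replicate 1. Prl3d1 had no entry in the table.

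Spongiotrophoblast and junctional zone markers also fell as a list (adjusted p = 0.00504; 0.530 as the adjusted p with an estimated correlation; 0.00369 without STZ replicate 1). Adjusted over the list alone, 4 of the 14 members fell and 0 rose: Tpbpa, Prl8a9, also in the prolactin list (1159 ± 403 CPM in control, 212 ± 118 in STZ), and the pregnancy-specific glycoprotein genes Psg29 (-2.21 ± 0.52) and Cgm4 (-2.04 ± 0.59). In the fit without STZ replicate 1, 7 fell and 1 rose, Psg19, Cited1 and Plac1 being added to the falls and Phlda2 (0.61) being the rise. The list median was -0.52, and Ascl2, a transcription factor of the spongiotrophoblast lineage, measured 57.9 ± 11.6 CPM in control and 42.0 ± 21.8 in STZ (-0.46 ± 0.44).

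Glycogen trophoblast markers fell as a list (11 of 11 members lower, median -0.57, adjusted p = 0.000215; adjusted p = 0.530 with an estimated correlation; 0.0163 without STZ replicate 1), although 0 members passed adjusted over the list alone (1 without STZ replicate 1, Ppp1r3c). Among them, the glycogen-targeting phosphatase subunit Ppp1r3c measured 41.6 ± 12.7 and 14.7 ± 5.45 CPM (-1.50 ± 0.37), the branching enzyme Gbe1 -0.58 ± 0.25, the glycogen synthase Gys1 -0.50 ± 0.36, Pcdh12 -0.67 ± 0.43, Cdkn1c -0.66 ± 0.42 and Igf2 -0.46 ± 0.39. The list median was -0.21 without STZ replicate 1. Giant cell markers passed narrowly (12 members, median -0.35 and -0.17 without STZ replicate 1, adjusted p = 0.0421; 0.530 as the adjusted p with an estimated correlation), with 1 member, the cathepsin Cts7, that fell adjusted over the list alone (17.9 ± 5.18 and 1.94 ± 1.197 CPM), joined by Ctsq without STZ replicate 1. This call was lost without control replicate 3 (adjusted p = 0.0630), STZ replicate 2 (0.0764) or STZ replicate 3 (0.0573) and with library totals as the only scaling (0.124), and the list's Hand1 measured 93.7 ± 3.03 and 72.1 ± 32.0 CPM. Invasive trophoblast markers passed with the 6 libraries (14 of 15 members lower, median -0.46, adjusted p = 0.000229; adjusted p = 0.530 with an estimated correlation) and did not without STZ replicate 1 (0.0990, median -0.20), with 0 members passing adjusted over the list alone, and without that library Plac1, lower, and Peg3, higher.

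Placental cathepsins and proteases did not pass as a list (20 members, adjusted p = 0.0942), and the test pointed lower while the median and mean log2 fold change were 0.04 and 0.06. Leaving out STZ replicate 1, the list passed as lower (adjusted p = 0.00884). With an estimated correlation the adjusted p was 0.530 for the 6 libraries and 0.401 without that library. Adjusted over the list alone, 3 members fell and 0 rose: Cts7 (-3.20 ± 0.51), Ctsm, from 498 ± 124 to 112 ± 66.4 CPM (-2.15 ± 0.54), and Ctsr (-1.30 ± 0.27). There were 5 without STZ replicate 1, with Ctsq and Timp2 added.

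Macrophage and leukocyte markers were higher in 14 of 15 members, with a median of 1.89 (adjusted p = 0.000215; adjusted p = 0.530 with an estimated correlation; 0.00884 without STZ replicate 1, where the median was 0.69), and 0 members passed adjusted over the list alone, against 2 that rose without STZ replicate 1, Ptprc and Lyz2. The list averaged 2.27, 0.74 and 0.19 log2 units above the control mean in STZ replicates 1 to 3, and 0.13 in control replicate 2. Lysozyme (Lyz2) measured 19.6 ± 2.14 CPM in control and 165, 55.5 and 38.1 CPM in STZ replicates 1 to 3. Its log2 fold change was 2.13, and 1.27 without STZ replicate 1. Uterine natural killer cell markers rose as a list (8 members, 6 higher, median 1.45, adjusted p = 0.0131; adjusted p = 0.530 with an estimated correlation; 0.00884 without STZ replicate 1, where the median was 0.73). Adjusted over the list alone, 3 of them rose and 0 fell: Prf1, from 11.4 ± 1.80 CPM to 131, 35.1 and 37.4 CPM, Nkg7 (2.12 ± 0.58), from 2.38 ± 0.510 CPM to 19.7, 5.10 and 6.27 CPM, and Cd96 (2.28 ± 0.72), from 1.49 ± 0.597 CPM to 14.9, 3.89 and 2.84 CPM. Without STZ replicate 1 the log2 fold changes were 1.27 for Nkg7 and 1.22 for Cd96, and Cd96 no longer passed adjusted over the list alone. The natural killer call was lost with unique reads (adjusted p = 0.0549) and with a replicate block (0.0603). The decidua markers that marked STZ replicate 1 moved with both lists, at the values given above.

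A further set of lists passed only with STZ replicate 1, the library in which decidua markers were highest. Decidua markers themselves were higher (12 of 13 members, median 2.12, adjusted p = 0.00251; adjusted p = 0.530 with an estimated correlation; 0.0978 without STZ replicate 1, where the median was 0.42), and Bmp2, a growth factor of the decidual reaction, rose adjusted over the list alone, with 22.3 ± 10.9 CPM against 4.61 ± 1.95. Higher with the 6 libraries were angiogenic factors and receptors (15 of 15 members, median 1.24, adjusted p = 0.000215), inflammation and cytokines (11 of 13, median 1.65, 0.000647), fatty acid oxidation and PPAR targets (15 of 18, median 0.38, 0.0131), smooth muscle markers (7 of 8, median 0.94, 0.0131), insulin and IGF signalling (16 of 19, median 0.57, 0.0163) and endothelial markers (10 of 11, median 1.03, 0.0200). For each of these lists the adjusted p was 0.530 with an estimated correlation, and without STZ replicate 1 it was 0.0603, 0.0780, 0.166, 0.195, 0.368 and 0.240 in that order. The medians without that library were 0.41, 0.92, 0.07, 0.27, 0.16 and 0.14. The endothelial call was also lost without control replicate 2 (0.0533) or 3 (0.122), and the insulin and IGF call without control replicate 2 (0.0732) or 3 (0.0795) or STZ replicate 2 (0.0562). Only Tagln, an actin-binding protein of smooth muscle, rose adjusted over the list alone among these 6 lists. It measured 2.09 ± 0.554 CPM in control and 17.5, 6.66 and 4.85 CPM in STZ replicates 1 to 3. Its log2 fold change was 2.19, and 1.46 without STZ replicate 1. Tagln and Esam rose and Igfbp2 fell in this way without STZ replicate 1.

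Among members of those lists, Vegfa measured 19.97 ± 2.99 CPM in control and 32.6 ± 3.47 in STZ (0.71 ± 0.19), but 5.38% of its control reads were unique, and with unique reads alone its log2 fold change was -0.44. That value rested on 36 control and 23 STZ reads (edgeR adjusted p = 0.690), too few to set a direction. Unique reads match only 1 transcript, so they also leave out reads that isoforms of the same gene share. The insulin receptor Insr measured 21.2 ± 6.10 and 35.6 ± 16.6 CPM, and its substrate Irs2 34.5 ± 4.19 and 83.7 ± 53.1. Irs2 was at 144, 64.5 and 42.9 CPM in STZ replicates 1 to 3. Its log2 fold change went from 1.28 to 0.65 without STZ replicate 1.

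Interferon response genes (17 of 20 higher, median 0.67, adjusted p = 0.0313) had an adjusted p of 0.769 with an estimated correlation, were lost without control replicate 1 (0.259) and pointed lower without STZ replicate 1 (0.538, median -0.05). Stromal fibroblast and matrix genes (11 of 16 higher, median 0.88, adjusted p = 0.0446) had an adjusted p of 0.644 with an estimated correlation and were lost without STZ replicate 1 (0.538, median 0.21), STZ replicate 2 (0.0914), control replicate 2 (0.266) or control replicate 3 (0.137). Cell cycle genes were lower in 22 of 24 members (median -0.26, adjusted p = 0.000646; adjusted p = 0.617 with an estimated correlation), which did not hold without STZ replicate 1 (0.638, median -0.03). In these 3 lists 0 members passed adjusted over the list alone, and without STZ replicate 1 Irf1 and Gbp2 rose and Fbln1 fell.

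**Figure D2:**
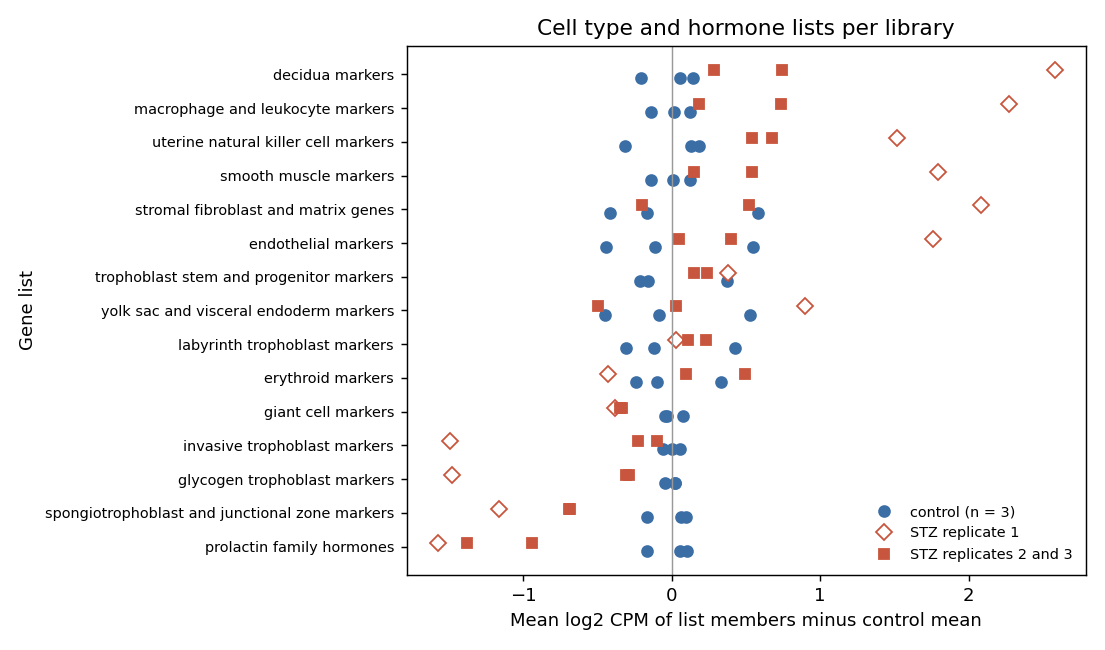
Mean log2 CPM of the members of 15 cell type and hormone lists in each library, minus the control mean, with controls as filled circles, STZ replicate 1 as open diamonds and STZ replicates 2 and 3 as filled squares. STZ replicate 1 lay at 2.58 for decidua markers and at -1.48 for glycogen trophoblast markers, where the other STZ libraries lay at 0.74 and 0.29 and at -0.29 and -0.31, while the prolactin family lay at -1.58, -1.38 and -0.94 in the 3 STZ libraries.

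Lists on glucose transport, glycogen metabolism and cell stress did not pass. Glucose transport and glycolysis had 21 members with a median of -0.13 (adjusted p = 0.318). The main placental glucose transporter Slc2a1 measured 289 ± 25.6 CPM in control and 218 ± 42.6 in STZ (-0.41 ± 0.20), and Slc2a3 39.0 ± 14.5 and 53.7 ± 11.9. Glycogen metabolism had a median of -0.01 over 24 members (adjusted p = 0.592), with the glycogen-binding protein Stbd1 at 66.0 ± 8.03 and 29.2 ± 10.3 CPM. The adjusted p was 0.0797 for cholesterol and fatty acid synthesis, 0.868 for hypoxia response, in which Hif1a measured 444 ± 29.4 and 398 ± 109 CPM, 0.876 for oxidative stress response, 0.441 for endoplasmic reticulum stress, 0.868 for heat shock genes, 0.167 for immediate early genes and 0.102 for amino acid transporters. It was 0.654 for imprinted genes and for erythroid markers, 0.592 for labyrinth trophoblast markers, 0.368 for trophoblast stem and progenitor markers, 0.857 for yolk sac markers and 0.868 for steroid synthesis. In these 15 lists 0 members passed adjusted over the list alone, except that the estrogen sulfotransferase gene ste2 of the steroid list fell (20.1 ± 5.46 and 6.55 ± 2.53 CPM). Without STZ replicate 1, Ppp1r3c, Stbd1, Sdf2l1, Dusp1, Btg2, Ctsq and ste2 fell and Acaca, Peg3, Zim1, Hspa1b, Star and Fdxr rose adjusted over their lists. The tests for endoplasmic reticulum stress and steroid synthesis pointed lower while their medians were 0.05 each.

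Some of these lists passed when a library was left out. Without STZ replicate 1 these were endoplasmic reticulum stress (lower, adjusted p = 0.00346), cholesterol and fatty acid synthesis (lower, 0.00884) and erythroid markers (higher, 0.0422). With an estimated correlation none of the 3 passed without that library (adjusted p = 0.401, 0.424 and 0.639 in that order). Without control replicate 1 they were amino acid transporters (0.0193), labyrinth trophoblast markers (0.0274) and trophoblast stem and progenitor markers (0.0483), and without control replicate 2 cholesterol and fatty acid synthesis (0.0284), none of them fitted with an estimated correlation. Sources of the replicates were not stated beyond their numbers, so all p-values measure the spread between these samples and not necessarily between litters.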

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

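The alternatives added after seeing the data are DESeq2 and camera with an estimated correlation, both without STZ replicate 1, limma-voom with sample quality weights, and principal components with each library left out. The count of genes past the threshold, 0 with edgeR, was 0 under the other normalisations, with the 1 CPM filter, with unique reads, with glmTreat and with the added 2-fold minimum. It was 4 with no filter and 4 at an adjusted p under 0.10 (Prl8a5, Prl8a7, Echs1 and Fam50a in both), 5 with either RPKM pseudocount (5 with 1 and 5 with 0.1; the same 4 and Actg1), 1 with limma-voom (Echs1), and 100 with DESeq2. DESeq2 without STZ replicate 1 called 210, and limma-voom with quality weights 1195, where STZ replicate 1 had a weight of 0.0925. The cause of these differences was not tested. In the simulated counts DESeq2 made 43 false calls and edgeR 5, but no simulated library stood apart, so these counts cannot explain the differences in the real libraries. Leaving out 1 library gave 0 to 1 genes and 10 to 19 lists. The list count of 17 was 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation without STZ replicate 1, and 14 to 17 under the other alternatives. The interferon list turned to lower without STZ replicate 1, with an adjusted p of 0.538 at the preset and 0.866 at an estimated correlation, and its range with 1 library left out was 0.000873 to 0.538. At the preset correlation the adjusted p ranged over the alternatives from 4.12e-09 to 1.73e-06 for the prolactin family, 0.00057 to 0.0477 for spongiotrophoblast, 3.6e-05 to 0.0163 for glycogen trophoblast and 4.3e-06 to 0.0149 for macrophage markers. Lists that no longer passed were giant cell markers with unique reads (0.0598) and RPKM (0.274 and 0.307), natural killer markers with unique reads (0.0549), inflammation with RPKM (0.117 and 0.114) and stromal genes with unique reads (0.0868) or no filter (0.0653). Lists that newly passed were cholesterol and fatty acid synthesis with library totals (0.0319) and placental cathepsins with no filter (0.0398). The first component held 67.8% with all genes and 38.2% to 76.6% with 1 library left out, the lowest without STZ replicate 1. RPKM moved the median log2 fold change of all genes to -0.22 and -0.26, so falls on that scale are read against it. Of 3379 pairs of a list or named gene with an alternative, 45 changed sign with both values short of the threshold.

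Replicate numbers showed no pairing of the samples: deviations of same-numbered libraries from their group means correlated at -0.01, -0.03 and 0.02. Control replicate 1 correlated best with STZ replicate 2 (0.07). Within the STZ group, the deviations of STZ replicate 1 correlated at -0.76 and -0.91 with those of STZ replicates 2 and 3. Those of control replicate 1 correlated at -0.69 and -0.73 with those of control replicates 2 and 3. Deviations from a group mean sum to 0, so negative values within a group are partly built in. Replicate 1 stood opposite the others in each group, most strongly in STZ, so the check could miss a pairing. With the replicate block edgeR called 0 genes (672 at an unadjusted p under 0.05) and camera 16 lists, the uterine natural killer list having an adjusted p of 0.0603.

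The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other 0, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 1007 genes and the highest other 1215, so 2 splits gave as many, the real one included. For lists the real split gave 17 and the others 7 to 14, so only the real split itself gave as many. Camera with the preset correlation thus passed at least 7 of the 33 lists in every split, so a passing list did not by itself mark the real grouping.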

Other observations

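Tests of STZ replicate 1, of the prolactin and spongiotrophoblast genes and of the genes that switch on or off were chosen only after the results were seen; the chromosome 17 test was set before its result was seen.

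Genes of the pregnancy-specific glycoprotein and CEACAM family, secreted and surface proteins of trophoblast, were picked by symbol after their values were seen, so they were not tested as a set. Of the 11 measured members, 4 of which are in a fixed list, 10 were lower in STZ and 1 higher (median log2 fold change -1.92, and between -1.92 and -1.91 under the other scalings; -1.57 without STZ replicate 1). Ceacam12 measured 425, 737 and 671 CPM in control and 30.8, 123 and 107 CPM in STZ replicates 1 to 3, and the log2 fold changes of Ceacam11 and Ceacam3 were -3.43 ± 0.56 and -1.92 ± 0.40. Ceacam9 measured 2088, 2180 and 2385 CPM in control and 658, 1911 and 1754 CPM in STZ, and Ceacam4 was high in STZ replicate 1 alone (335 CPM against at most 38.9 elsewhere).

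Granzyme genes were picked in the same way and were not tested as a set either. Of the 4 measured, 2 were higher and 2 lower (median 0.89, and 0.37 without STZ replicate 1), with Gzma at -1.19 ± 0.68. The prolactin, cathepsin and Tpbpa clusters share chromosome 17, but the other 406 genes on it had a median log2 fold change of -0.0290 without STZ replicate 1, against -0.63 for the 29 cluster genes, which speaks against a change of the whole chromosome.

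STZ replicate 1 stood apart from the rest. Its 10744260 reads lay between those of the other libraries (8108505 to 13185888), which argues against library size. More decidual tissue in the dissected piece is a candidate explanation: 10 of 13 decidua markers were highest there, Prl8a2 (7918 CPM) and Des (7288 CPM) being the most abundant, and 34 of 45 trophoblast markers were lowest. All 13 decidua markers also averaged 1 CPM or more in control, and 4 of them are in another list. The share of all genes highest or lowest in this library was not counted, so these counts lack a reference. Y chromosome reads were fewest there (1228, against 2620 to 4403 in the other libraries), but they also depend on the sex of the conceptuses. A control sample under the wrong label stays open. The 18 genes that fell without this library stood in it, relative to Krt8 and Krt18, at a median of -0.84 log2 units from control. In the other STZ libraries the medians were -1.32 and -1.45. The choice of genes favours larger falls there, since the 18 were picked for falling in those libraries. A stronger response of this placenta to STZ was not tested.

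The 9 prolactin and spongiotrophoblast genes that fell adjusted over their lists had a median log2 fold change of -2.38 without STZ replicate 1. A smaller share of trophoblast in the samples would lower all trophoblast genes alike. The 31 trophoblast markers of at least 100 CPM in control had a median of -0.20 (SD 0.75) without STZ replicate 1, so as a whole they fell little. Krt8 and Krt18 took 0.391% and 0.338% of the reads in STZ replicate 2 and 0.460% and 0.398% in STZ replicate 3. The controls lay at 0.344% to 0.432% and 0.327% to 0.355%. For the 9 genes as a set, these values argue against less trophoblast as the only cause of their falls in those 2 libraries. The question stays open for Prl2b1, whose -0.89 in that fit lay within the spread of the markers. The 9 were picked for falling, which widens the gap, and Tpbpa and Prl8a9 are also among the 31. Reads shared between paralogs are argued against as the cause for the set: 4 of the genes had only unique reads, and the median of the other 5 was -3.18 with unique reads, against -3.31 with all reads (Prl8a5 -4.12 and Prl8a7 -4.03 with unique reads). For Prl2b1 this stays open, since its value went from -0.93 to -0.58, and Cgm4 went from -2.04 to -1.77. Fewer spongiotrophoblast cells, lower expression per cell and a difference in developmental stage between the groups all stay open and untested, and the effect of STZ may act through any of them.

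A set of 59 genes had at most 2 reads in some library and at least 100 in another. Of the 47 with a single listed transcript, where shared reads must belong to another gene, 28 had under 10% unique reads, Echs1, Fam50a and Actg1 included, which is 59.6% against 2.08% of 7823 other such genes of at least 200 reads, so assignment of reads that match several places is a likely cause for these 28. It stays open for 9 genes of more than 1 transcript with as few unique reads, since their isoforms share reads and 7 of the 9 were highest in STZ replicate 1, and it is argued against for 20 others, whose median share of unique reads was 100%. All 20 were highest in STZ replicate 1 (15) or STZ replicate 2 (5) and had at most 6 reads in STZ replicate 3, so an effect of STZ and more decidual tissue in those libraries both stay open for them, while 2 genes lay between. Of the 28, 3 stood at 12 reads or fewer in all of one group and at 20 or more in all of the other, and for these an effect of the groups stays open beside read assignment. The limit of 12 reads was set after the values were seen and equals the count of Actg1 in STZ replicate 1.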
